A study of Caenorhabditis elegans with 2 samples.

How the data were processed

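DNA precipitated with LIR-1, a zinc-finger protein related to LIN-26, was measured by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans. Per the labels, the animals carried an EGFP-tagged lir-1 made by CRISPR insertion at the gene itself, were collected as young adults at 63 hours after a start from starved first-stage larvae, and the chromatin was sheared by sonication and precipitated with an antibody against GFP. The series held 2 libraries, labelled as biological replicates 1 and 2 of 1 group. There was no second group, so no comparison between conditions was made, and the spread between the replicates is the error given.

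The deposited files were peak lists on the ce11 assembly, per the labels. For each library there was a ranked list of all peaks and a shorter list past a threshold on the irreproducible discovery rate (IDR), and for the series, where the peaks came from both libraries together, there were 2 ranked lists and 2 sets past a threshold, 1 of them named conservative by the authors. Per the manifests deposited with the samples, each list was derived from filtered alignments of the library or libraries and from a control alignment, which was not analysed here. The aligner, the peak caller, their versions, and how reads with several matches in the genome were treated are not given in the sources used here. The height of a peak is a score that the authors' peak caller wrote, called signal in the text; how the caller scaled it is not given in the sources used here. The deposited ranked lists also held −log10 of the global IDR for each peak. These scores and IDR values are the authors' own and were used to describe, rank and filter peaks within a list. The files give no read totals, so the depth of each library is unknown. Tested on the files, all 1209 peaks of the conservative set were rows of the ranked list that compared the libraries, with a global IDR of 0.00997 or lower, and 2 other rows at that limit were left out of the set.

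Coordinates are 1-based on ce11, which is the same assembly as WBcel235. All peaks ended within the chromosome lengths of the reference genome used, and gene models came from Ensembl release 115. The main set was the conservative set, whose peaks are called sites. A site was placed by its summit: promoter (1000 bp upstream to 200 bp downstream of a protein-coding 5′ end), then exon, intron or intergenic sequence. Shares were set against 1000 circular shifts of the sites along their chromosomes (two-sided permutation test). The overlap of the replicates' lists was set against 1000 such shifts (one-sided permutation test). Chromosomes were compared with their lengths by two-sided exact binomial tests. A gene was counted as having a site when a summit lay in its promoter window. Shares of genes with a site were compared by two-sided Fisher's exact tests, for 11 annotation classes and for 24 gene lists. Sequence was read in 101 bp windows round the summits, and the share of windows with each of 2080 6-mers (a 6-mer and its reverse complement counted as 1) or each of 8 motifs was compared by two-sided Fisher's exact tests with windows centred 500 bp to either side. The shares of chromosomes, classes, lists, 6-mers and motifs were adjusted within each family by the Benjamini-Hochberg method, with a threshold of 0.05. Signal at promoter sites and other sites was compared by a two-sided permutation test of the difference in median log2 signal with 100000 permutations. Intervals are exact binomial (Clopper-Pearson) 95% intervals. The intervals and the exact tests treat genes, windows and sites as independent, which neighbours are not.

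The lists, the motifs and the genes to be named were fixed before the data were examined. The named genes are those with the nearest 5′ end to the 20 strongest sites, the 4 genes lir-1, lir-2, lir-3 and lin-26, and up to 3 members of each list with the strongest sites. The counts of sites beside small RNA genes, the split by ribosomal subunit and the comparison with the places of protein-coding genes were added after the data were seen. At most 5 6-mers of lowest p and all fixed motifs are named. Of the listed symbols, 1 heterochronic gene has another name in the annotation and was matched by its place in RefSeq, and daf-21 was counted under its current name among the hsp genes. Alternatives fixed at the same time were the other series set, the stronger 50% of sites, the list of either replicate alone, merging of overlapping peaks, other promoter windows, nearest-gene assignment, other overlap rules, narrower sequence windows and other backgrounds. For a named site, the mean ± SD is over the signal in the ranked lists of both replicates, and these values were not compared with the signal of both libraries together.

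The tests were tried on simulated data first. For gene lists, drawn from 19973 protein-coding genes, 100 of 100 lists with planted sites and 0 of 380 lists without were called. These lists were random draws with genes marked independently, and sites were planted at 40% of members, only in lists of 20 or more genes. The trial therefore does not cover clustered families that share a site, smaller lists or weaker excesses. For 6-mers, 5 of 5 planted in 1209 windows were recovered and 0 of 2080 were called in windows at random places. Beside the planted ones, 29 of the other 2075 were also called, so a few motifs bring further calls. These windows were placed without regard to base composition, whereas the real summits were richer in G and C than their flanks. The 6-mer trial therefore does not cover calls that follow from base composition. For the genomic distribution, 20 of 20 sets with planted promoter sites and 1 of 20 random sets passed the threshold. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.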

Results

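The data describe where chromatin of young adult C. elegans was precipitated with tagged LIR-1. No library from untagged animals was analysed here, so a site is a place of reproducible precipitation, and binding was not told apart from other causes of it. The conservative set held 1209 sites, all on the 6 nuclear chromosomes, with a median width of 280 bp, and covered 0.327% of the genome. Replicate 1's own list held 834 peaks and replicate 2's own list held 580. Signal at the sites ran from 2.18 to 468.8 with a median of 86.4.

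The replicates marked largely the same places. Of replicate 2's 580 peaks, 424 (73.1%) overlapped a nuclear peak of replicate 1 by 1 bp or more, against a mean of 0.442% after circular shifts. In the other direction, 425 of 828 nuclear peaks (51.3%) overlapped, against 0.291%. No shift reached either value, and p = 0.001 in both directions (one-sided permutation test) is the smallest that 1000 shifts can give. Of the 1209 sites, 440 lay in both own lists and had a median signal of 129, while 380 lay in neither and had a median of 70.5. Across these sites the signals of the libraries had a Spearman's rho of 0.56 and a Pearson's r of log2 signal of 0.74. The permutation p was 1e-05 for each, the smallest that 100000 permutations can give; the relation is across sites, which are not independent replicates. The sites were themselves chosen by an IDR threshold, which asks for agreement between these libraries, so the correlations over them are no independent measure of it. Over all 36486 ranked peaks rho was 0.27.

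The first question was which kinds of sequence held the sites. Promoters of protein-coding genes held 664 of the 1209 sites, or 54.9% (95% interval 52.1 to 57.8), against 21.2% for shifted sites. Exons held 53 sites (4.38% against 23.2%), introns 244 (20.2% against 31.0%) and intergenic sequence 248 (20.5% against 24.6%). Promoter sites lay close to the gene: 507 sites, 41.9% of all, were within 500 bp upstream of the nearest protein-coding 5′ end, and the median promoter site lay 215 bp upstream of it. The excess at promoters and the deficits in exons and introns had p = 0.001, the smallest the shifts can give, and the intergenic deficit had p = 0.006 (two-sided permutation test). The intergenic deficit was not seen with a narrower promoter window of 500 bp upstream and 100 bp downstream, where 28.8% of sites against 29.4% were intergenic (p = 0.737, permutation test).

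**Figure D1:**
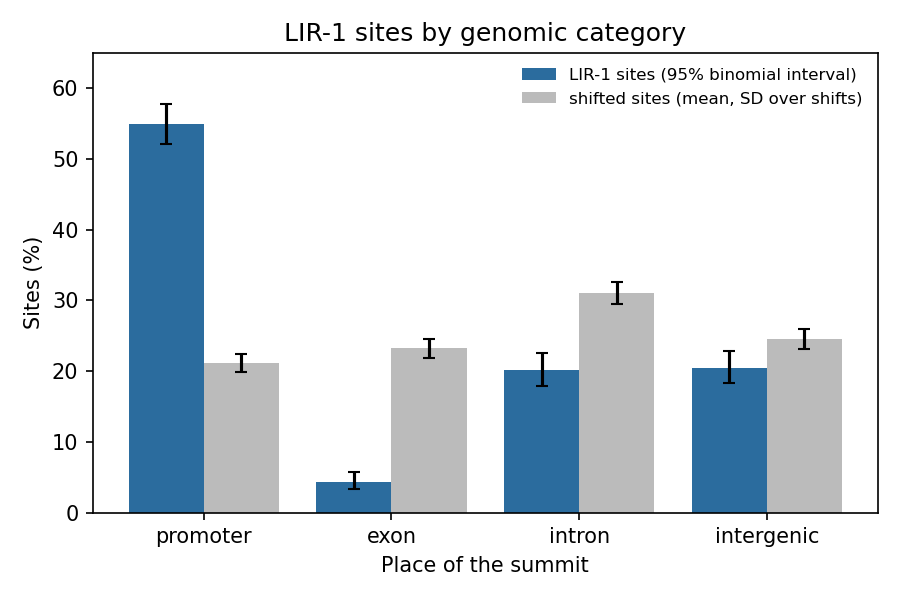
Percent of LIR-1 sites (y axis) with the summit in a protein-coding promoter, exon, intron or intergenic sequence (x axis), with 95% binomial intervals in blue, beside the mean and SD over 1000 circular shifts in grey. Promoters held 54.9% of sites against 21.2% of shifted sites, and exons held 4.38% against 23.2%.

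Promoter sites were stronger than other sites. The median signal was 92.5 at the 664 promoter sites and 81.1 at the 545 others, a difference of 0.19 on the log2 scale (p = 1e-05, two-sided permutation test, the smallest that 100000 permutations can give). In replicate 2's list alone the difference was 0.12 (p = 0.00991, permutation test). Of the 20 strongest sites, 15 lay in promoters, 1 in an intron and 4 in intergenic sequence.

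The strongest site lay on chromosome X at 9958623 to 9958868, 213 bp upstream of ZC506.1 (WBGene00013919), with a signal of 468.8 and a replicate mean of 230.4 ± 33.4 (SD, n = 2). The next was on X at 7265002 to 7265274, 520 bp upstream of F46H5.2 (WBGene00018518), with a signal of 448.2 (216.4 ± 30.8, n = 2). The third, on III at 10759142 to 10759360, lay 51 bp upstream of tasp-1, which encodes a threonine aspartase, with a signal of 407.8 (198.1 ± 9.81, n = 2). Genes for proteins of the large ribosomal subunit came next and recurred. The rpl-3 site (III, 3867473 to 3867666, 293 bp upstream) had a signal of 405.0, the rpl-15 site (IV, 654815 to 654996, 340 bp upstream) 349.0 and the rpl-35 site (III, 7854620 to 7854781, 448 bp upstream) 327.3. Their replicate means were 198.2 ± 0.889, 176.8 ± 20.7 and 158.6 ± 7.55 (SD, n = 2). Other promoters among the strongest belonged to mog-4, an RNA helicase gene of the germline sperm-to-oocyte switch (signal 330.5), ain-1, which acts with microRNAs (330.1), and cdc-48.1, an AAA ATPase of protein turnover (328.2). Those of Y17G9B.5 (305.8), spc-1, which encodes alpha spectrin (294.0), bet-2, a bromodomain gene (282.7), and eel-1, a ubiquitin ligase gene (280.9), followed.

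At 3 of the 20 strongest sites the nearest 5′ end was that of a noncoding RNA gene, and at 1 that of a pseudogene. T04C10.8 lay 13 bp from its summit, with epn-1 as the nearest protein-coding gene (signal 364.9), and T13H2.9 lay 2 bp away, with spat-3 (351.0). F16A11.7 lay 3 bp from a summit in an intron on chromosome I at 9382983 (364.4), and the pseudogene WBGene00023318 lay 1083 bp from an intergenic summit on chromosome II at 4048046 (279.2). The other 3 intergenic sites were 2539 bp upstream of hda-4, a histone deacetylase gene (378.0), 2287 bp upstream of Y39E4B.6 (326.3) and 1176 bp downstream of the 5′ end of F40E3.3 (285.8).

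Genes for small structural RNAs had a site more often than other genes. Of 612 tRNA genes, 151 (24.7%, interval 21.3 to 28.3) had a site in the promoter window, against 3.12% of all other genes. Of 346 snoRNA genes, whose products guide RNA modification, 81 (23.4%) had one, as did 20 of 129 snRNA genes (15.5%), whose products act in splicing. Protein-coding genes stood at 883 of 19973 (4.42%). piRNA genes, at 69 of 15363 (0.449%), and pseudogenes, at 22 of 2128 (1.03%), had a site less often than other genes, and 0 of 20 rRNA genes had a site. Adjusted p over 11 classes (Fisher's exact test, two-sided) was 5.10e-84 for tRNA genes, 2.98e-43 for snoRNA genes, 2.88e-08 for snRNA genes, 5.26e-178 for piRNA genes and 3.58e-12 for pseudogenes. The shares were smaller in the shorter lists of replicates 2 and 1 alone, at 11.9% and 14.5% for tRNA genes, 13.9% and 16.5% for snoRNA genes and 2.39% and 3.50% for protein-coding genes. They were 0.182% and 0.267% for piRNA genes, 0.376% and 0.705% for pseudogenes and 4.60% and 7.28% for miRNA genes, and each of these classes passed in both. Among the stronger 50% of sites, 65 tRNA genes (10.6%) had one, with an odds ratio of 6.17 in place of 10.2, and 2.71% of protein-coding genes. Many tRNA genes have identical copies, so which copy held the site is uncertain. A summit counted for every gene whose window held it, so the 1594 genes of any kind with a site are not independent. The p-values treat genes as independent and overstate the evidence where genes of a class lie close together.

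Within 200 bp of a tRNA 5′ end there were 125 sites, and at 85 of them the summit lay inside the tRNA gene, at a median of 23 bp downstream of the 5′ end. Beside snoRNA genes the summits lay mostly upstream, at 44 of 62 sites, and the median over the 62 was -20 bp. Sites beside tRNA genes had a median signal of 82.0 and those beside snoRNA genes 94.7. Of the 545 sites outside protein-coding promoters, 148 (27.2%) were within 200 bp of the 5′ end of a tRNA, snRNA or snoRNA gene.

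**Figure D2:**
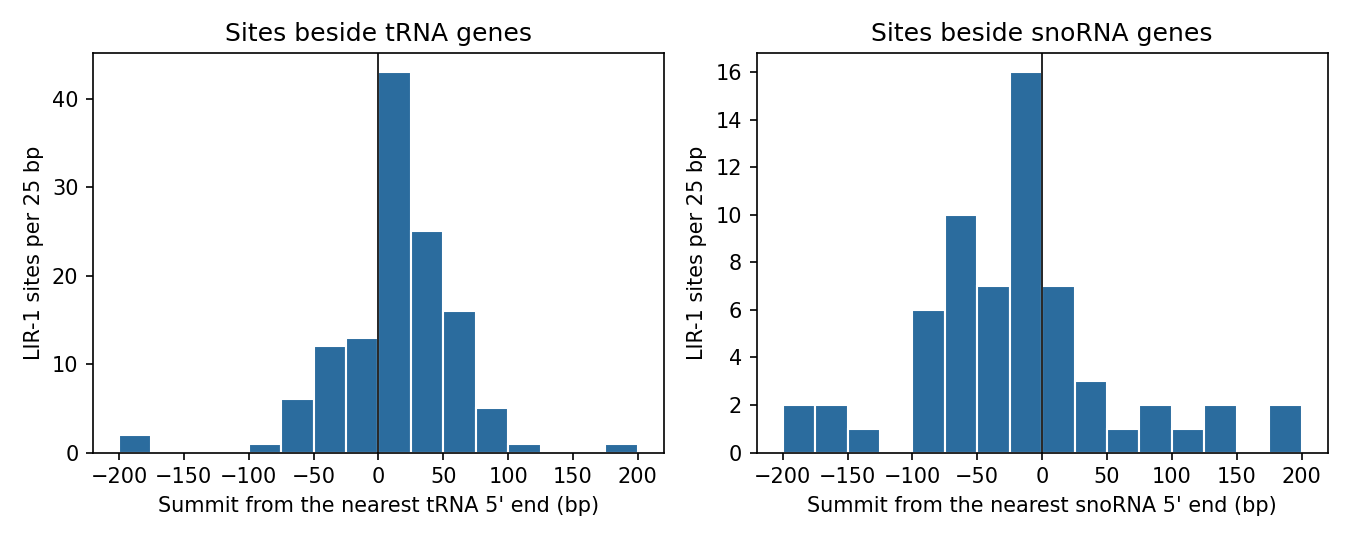
Number of LIR-1 sites per 25 bp (y axis) by the distance of the summit from the nearest tRNA (left) or snoRNA (right) 5′ end in bp (x axis, negative upstream, vertical line at the 5′ end). The fullest tRNA bin, 43 sites, begins at the 5′ end, and the fullest snoRNA bin, 16 sites, ends just upstream of it.

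miRNA genes (24 of 261, 9.20%; adjusted p = 1.61e-05, Fisher's exact test) and other noncoding RNA genes (333 of 7764, 4.29%; adjusted p = 6.62e-06) also passed the threshold. The other genes that each of these classes was compared with include the 15363 piRNA genes, at 0.449%. Noncoding RNA genes stood above the 3.22% of all other genes, but not above the 4.42% of protein-coding genes. Counted by a summit in the gene or within 100 bp of it, miRNA genes stood at 2.68% and no longer passed (adjusted p = 0.697, exact test), and counted by the nearest 5′ end neither class passed (miRNA 3.07%, adjusted p = 0.250; noncoding RNA 1.92%, adjusted p = 0.789). From replicate 1's list alone, other noncoding RNA genes stood at 2.82% (adjusted p = 0.0634, exact test), and from replicate 2's at 2.36%, past the threshold (adjusted p = 0.000207, exact test). lincRNA genes (9 of 194, 4.64%) and antisense RNA genes (2 of 100, 2.00%) did not pass.

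Of the 24 gene lists, 7 had a higher share of members with a site than other genes past the threshold and 4 had a lower one. Ribosomal protein genes led by number: 33 of 78 (42.3%, interval 31.2 to 54.02) had a site, against 4.27% of other protein-coding genes (odds ratio 16.4, adjusted p = 4.39e-23, Fisher's exact test). Both subunits were represented, with 20 of 47 rpl genes and 13 of 31 rps genes. In the lists of replicates 2 and 1 alone the share of ribosomal protein genes was 21.8% and 32.1%, past the threshold in both. Counted by the nearest 5′ end it was 28.2% (odds ratio 12.5 in place of 16.4), also past the threshold. Of the spliced leader RNA genes, whose products are joined to the start of many worm mRNAs, 11 of 30 (36.7%) had a site, against 3.38% of all other genes (adjusted p = 1.63e-08, Fisher's exact test). The strongest were at sls-2.1 (signal 193.9, 100.2 ± 7.05), sls-2.2 (162.0, 80.4 ± 10.4) and sls-2.4 (146.8, 67.1 ± 2.22; SD, n = 2), with summits 36, 25 and 4 bp upstream. Of the 30 genes, 18, these among them, have a sequence of their own in the annotation, and 12 of the sls-1 type share theirs.

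The Rb and DREAM complex genes, which encode repressors of cell-cycle and germline genes, had a site at 5 of 8 (62.5%, interval 24.5 to 91.5; adjusted p = 5.02e-05, Fisher's exact test). The strongest were lin-54 (signal 239.4, 116.0 ± 4.12), lin-53 (204.3, 96.4 ± 12.1) and lin-9 (121.3, 59.7 ± 12.5; SD, n = 2), followed by lin-35 (121.2) and efl-1 (80.4). Chaperone genes had one at 11 of 51 (21.6%; adjusted p = 5.34e-05, exact test), led by hsp-60 of the mitochondria (243.7, 118.8 ± 4.74), hsp-1 of the cytosol (229.6, 115.0 ± 18.2) and hsp-3 of the endoplasmic reticulum (216.7, 108.0 ± 24.2). By the nearest 5′ end chaperone genes stood at 11.8% (odds ratio 4.13 in place of 6.01; adjusted p = 0.0177, exact test). The sites of hsp-60 and prp-19 lay outside the narrower promoter window. Mitochondrial respiratory chain genes had one at 6 of 26 (23.1%; adjusted p = 0.00271, exact test), led by cox-5A (230.4, 118.3 ± 8.28), cox-5B (180.1, 86.2 ± 2.58) and atp-1 (151.3, 75.6 ± 1.55). Germline genes had one at 6 of 25 (24.0%; adjusted p = 0.00252, exact test), led by the P granule helicase glh-2 (117.0, 61.4 ± 1.79), cgh-1 (96.1, 45.9 ± 16.1) and pos-1 (92.7, 44.7 ± 7.38). Splicing factor genes had one at 4 of 20 (20%; adjusted p = 0.0250, exact test), led by prp-19 (258.7, 129.7 ± 12.8), snr-1 (126.6, 61.4 ± 7.57) and snr-4 (124.0, 60.8 ± 7.27), followed by prp-8 (102.5). In replicate 2's list alone, Rb and DREAM genes stood at 37.5% (adjusted p = 0.00335, exact test), germline genes at 4% (odds ratio 1.70 in place of 6.87; adjusted p = 0.779, exact test) and respiratory chain genes at 11.5% (odds ratio 5.35 in place of 6.52; adjusted p = 0.0636, exact test). Splicing factors missed the threshold with the narrower promoter window (15%, odds ratio 4.96 in place of 5.425, adjusted p = 0.0657) and by the nearest 5′ end (10%, odds ratio 3.425, adjusted p = 0.240), and germline genes among the stronger 50% of sites (12%, odds ratio 4.91, adjusted p = 0.0783, Fisher's exact tests).

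Large families of genes with restricted expression had few sites. Chemoreceptor genes had one at 6 of 1292 (0.464%, interval 0.171 to 1.01; odds ratio 0.0947, adjusted p = 1.14e-17, Fisher's exact test) and C-type lectin genes at 2 of 240 (0.833%; adjusted p = 0.00715). F-box genes stood at 5 of 322 (1.55%; adjusted p = 0.0230) and nuclear hormone receptor genes at 4 of 269 (1.49%; adjusted p = 0.0339, exact tests). In each replicate's list alone 3 chemoreceptor genes (0.232%) had a site, and lectins had 0 in replicate 2's and 1 in replicate 1's, with both lists still past the threshold. The last 2 lists passed in neither replicate's list alone: F-box genes had adjusted p of 0.209 in replicate 2's list and 0.128 in replicate 1's, and nuclear hormone receptor genes 0.450 and 0.168 (exact tests). The odds ratios stayed low there, at 0.380 and 0.430 for F-box genes (0.337 in the full set) and 0.457 and 0.412 for nuclear hormone receptor genes (0.323). By the nearest 5′ end both had 0.1135, among the stronger 50% of sites both had 0.236, and in the other series set nuclear hormone receptor genes had 0.116 (exact tests). The strongest exceptions were sri-5 (signal 122.1), sre-23 (115.4) and srh-269 (96.5) among chemoreceptors and clec-126 (84.6) and clec-88 (72.6) among lectins. Among F-box genes they were fbxb-85 (169.2), fbxb-58 (150.1) and fbxa-83 (126.5), ahead of fbxb-72 (92.5) and fbxa-90 (80.4, the site it shares with efl-1), and among nuclear hormone receptors nhr-47 (141.3), nhr-142 (111.3) and nhr-255 (103.2), ahead of nhr-35 (78.9). The members placed after the first 3 of a list were named after their values were seen.

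Markers of single tissues were mostly without sites. None of 18 epidermal regulator and junction genes, 17 body-wall muscle genes, 20 neuronal genes, 7 pharyngeal genes or 31 major sperm protein genes had one. Intestinal genes had 1 of 18, the GATA factor gene elt-2 (signal 67.9). Cuticle collagens had 2 of 176, col-71 (103.1) and bli-6 (59.5), just outside the threshold (1.14%; adjusted p = 0.0520, Fisher's exact test). The 5 tissue lists with no site did not differ detectably from other protein-coding genes (adjusted p from 0.970 to 1, exact tests), nor did the intestinal list (adjusted p = 0.891). The remaining lists did not pass either (adjusted p from 0.328 to 1, exact tests). Proteasome subunits had 3 of 33, rpn-3 (133.7), rpn-11 (105.9) and rpn-9 (92.5). Histones had 3 of 72, his-37 (165.7) and the pair his-67 and his-68, which share a site (106.2). Homeobox genes had 2 of 63, ceh-38 (100.3) and ceh-43 (71.3), and heterochronic genes 1 of 13, lin-46 (74.6). Stress and lifespan regulators had 0 of 11, and 1, xbp-1, in replicate 1's list alone, named after its value was seen.

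**Figure D3:**
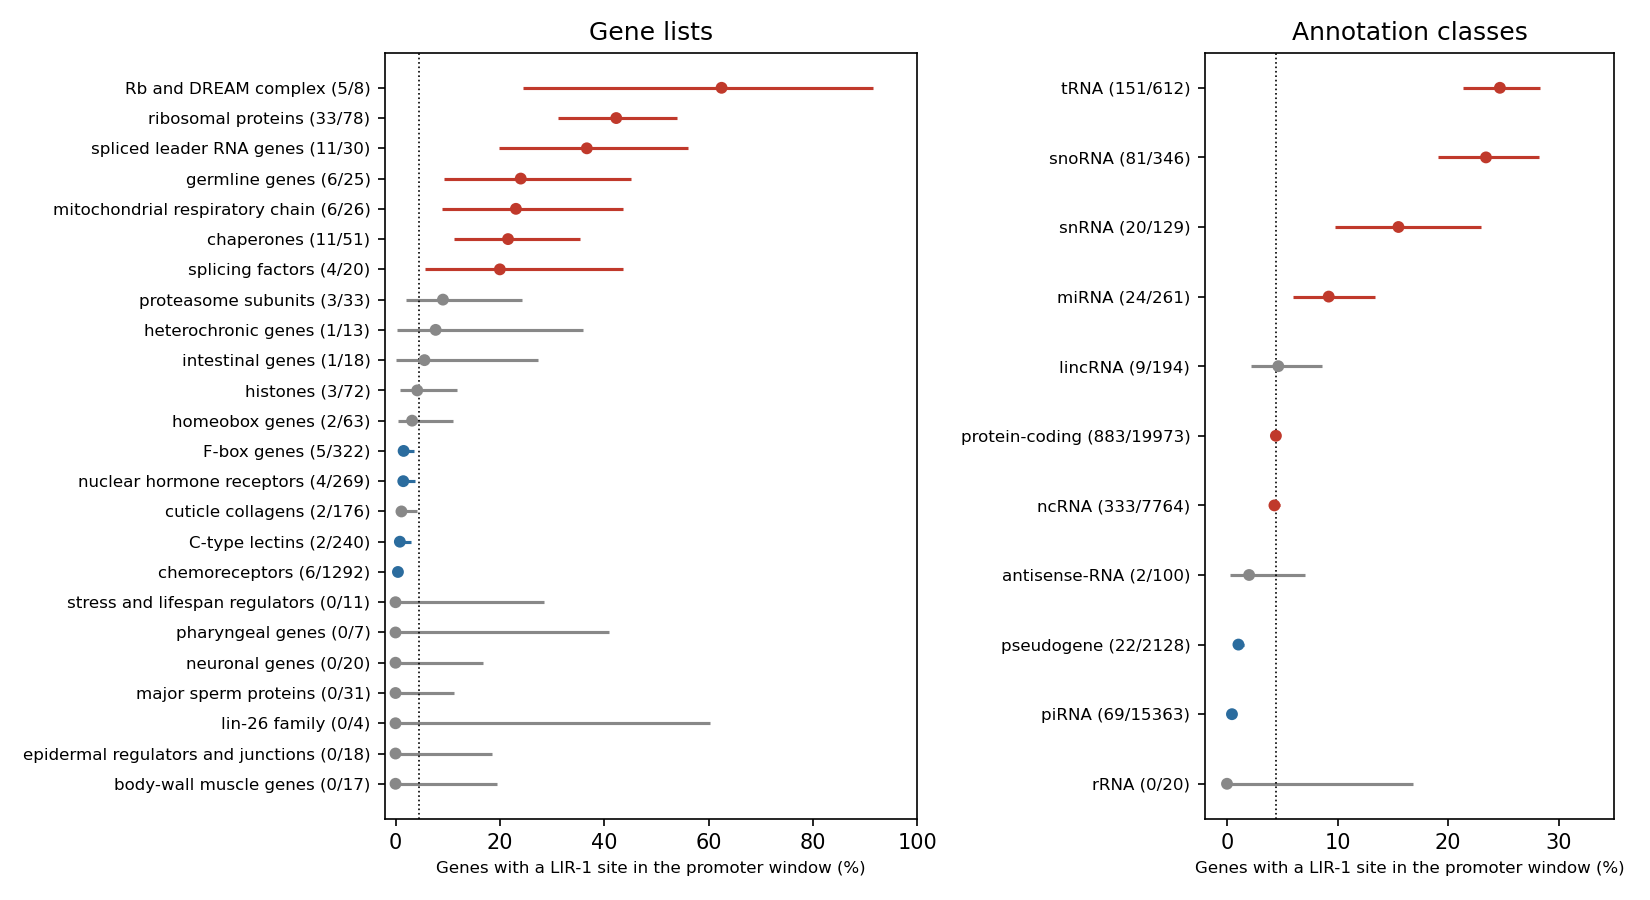
Percent of genes with a LIR-1 site in the promoter window (x axis) for each gene list (left) and annotation class (right), with 95% binomial intervals and the counts beside each name. Red and blue mark shares above and below those of other genes past an adjusted p of 0.05, and the dotted line marks the 4.42% of protein-coding genes; the highest list is the Rb and DREAM complex at 62.5%.

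LIR-1 had no site in the promoter window of its own gene or of its relatives. For lir-1 (WBGene00003044, II, 7672005 to 7682363) and lin-26 (WBGene00003012, II, 7682198 to 7684764), which overlap in the annotation, and for lir-3 (WBGene00003046, II, 11183075 to 11184807), the window held 0 of the peaks ranked between the libraries. For lir-2 (WBGene00003045, II, 7667267 to 7671909) it held 2, the stronger with a signal of 37.3 and an IDR of 0.392. The windows of lir-1 and lin-26 reach into the gene before them on the same strand, lir-2 and lir-1. They need not be the promoters in use, so the lack of sites there says little about these genes. The strongest ranked peak inside the lir-1 gene had a signal of 54.1 and an IDR of 0.135, against a median signal of 28.4 over all ranked peaks.

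Sites were unevenly spread over chromosomes. Chromosome I held 18.2% of sites for 15.03% of the length (adjusted p = 0.00506, exact binomial test) and III held 17.2% for 13.8% (adjusted p = 0.00212). Chromosome V held 15.2% for 20.9% (adjusted p = 4.10e-06, exact binomial test) and IV held 14.97% for 17.5% (adjusted p = 0.0344). X held 17.9% for 17.7% and II held 16.5% for 15.2%, neither past the threshold (exact binomial tests, 6 chromosomes). In replicate 2's list alone, only V passed, and I (17.8% of sites, adjusted p = 0.143), III (17.2%, 0.0554) and IV (16.6%, 0.622) did not, although the shares of I and III hardly moved; IV also missed it in replicate 1's list (0.435), in the other series set (0.113), among the stronger 50% of sites (0.830) and with overlapping peaks merged (0.0793, exact binomial tests). Against the shares of protein-coding genes in place of length, X held more sites (17.9% against 13.7%; adjusted p = 9.83e-05, exact binomial test), IV did not pass (adjusted p = 0.224), and I, III and V kept their direction and passed. The excess on X by this measure missed the threshold among the stronger 50% of sites (adjusted p = 0.0662, exact binomial test). The middle 33.3% of the length of the chromosomes held 39.7% of sites (p = 3.96e-06, exact binomial test); they also hold 37.8% of protein-coding genes, from which the sites did not differ detectably (p = 0.172).

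The sequence round the summits was rich in G and C, at 48.7% ± 7.46 (SD over 1209 windows) against 37.2% ± 8.83 in the flanks. Of all 6-mers tested, 574 were more frequent at summits and 494 less frequent at an adjusted p under 0.05, and 430 of the 574 had 4 or more G or C. The 6-mer of lowest p was ACGCGC, in 14.5% of summit windows and 1.28% of flank windows (odds ratio 13.0, adjusted p = 8.32e-53, Fisher's exact test). ACGCAG followed (15.7% against 2.40%), then GCGCGC (11.9% against 1.16%), GACGCA (14.8% against 2.36%) and CGCGCA (13.2% against 1.74%), with adjusted p from 1.62e-44 to 1.44e-40.

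Of the 8 fixed motifs, 4 were more frequent at summits. GAGA repeats were in 20.3% of summit windows and 6.33% of flanks (adjusted p = 1.48e-33, Fisher's exact test). The core of the B box, an internal promoter element of tRNA genes, was in 5.79% against 0.827% (adjusted p = 6.91e-18), a GC box in 6.12% against 1.90% (adjusted p = 3.12e-10) and the E-box in 5.54% against 2.03% (adjusted p = 7.70e-08, exact tests). Runs of T (7.78% against 19.02%), GATA sites (12.1% against 18.8%) and heat shock elements (2.98% against 7.40%) were less frequent, with adjusted p of 8.34e-20, 1.99e-07 and 3.98e-08. The core of the motif upstream of piRNA genes was in 0.248% against 0.744% (adjusted p = 0.0666, exact test). Against promoters of genes with no site, heat shock elements no longer differed past the threshold (3.69% against 5.38%, adjusted p = 0.116, exact test). The motifs were not compared with a background of the same GC count. Summit windows were richer in G and C than flanks (48.7% against 37.2%), so these differences cannot be told apart from base composition.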

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

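The tests of neighbouring promoters, of an untagged control and of shoulders were chosen after the results were seen; the tests of identical copies, base composition and signal in a single library were written before theirs. Replicate 1's own list held 6 peaks on mitochondrial DNA, with signals from 19.3 to 58.0, while the own list of replicate 2 and both series sets held 0. These 6 are among the 834 peaks counted for that list and entered no comparison of positions, genes or sequence; the difference between the replicates was not tested.

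The sites at tRNA genes may reflect binding there or a technical source. Neighbouring protein-coding promoters do not account for them: among the 491 tRNA genes outside every such promoter window, 19.6% (interval 16.1 to 23.3) had a site in or within 100 bp of the gene. This was above the 4.42% of protein-coding genes with a site in the promoter window, and above the 2.34% with a site in or within 100 bp of the gene. Reads shared between identical copies are not the whole source either. Of the 143 tRNA genes with a sequence of their own, 13.3% (interval 8.19 to 19.97) had a site in or within 100 bp. This was lower than the 23.9% of genes with a shared sequence. Genes that differ by a few bases count here as having a sequence of their own, and how reads with several matches were treated is unknown. Reads shared between similar copies are therefore not excluded. Accessible or heavily transcribed chromatin that precipitates without the tagged protein stays open and cannot be told apart from binding, because 0 libraries from untagged animals were analysed here. No biological explanation was tested, since the design holds 1 group.

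The GC-rich 6-mers may follow from base composition or from a preferred sequence. Against peaks below the threshold with the same GC count, the odds ratio of ACGCGC was 3.62 (95% interval 2.80 to 4.70), so GC count alone does not account for it. The odds ratio was far below the 13.0 against flanks, and ACGCGC had been picked by its low p in these same windows. Peaks below the threshold lay in promoters less often (23.5% against 54.9%), and no background matched both GC count and location. Other features of promoter sequence therefore stay open. Among the 60 6-mers of the same base composition it ranked 3 by odds ratio in that comparison. Whether the 6-mers are bound by LIR-1 itself or by partners at the same promoters was not tested.

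The 44 sites with a signal under 25 had a median signal of 9.16, against 87.8 for the other sites. They are likely shoulders of stronger sites: 100% had a stronger site of the set within 250 bp, at 199 to 222 bp, against 0.601% of the other sites. The weaker library's signal at these sites had a median of 36.0, against 38.3 at the other sites, but that test decides nothing about signal in a single library, because the IDR threshold already requires signal in both. Whether any of them is a separate binding event stays open.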

How the results depend on the processing

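Of the 58 recomputed values of the main results under alternatives, 53 stayed the same in direction and side of the threshold or within 1.5 times the count. The ratio of promoter sites to expectation, 2.59, ran from 1.65 with the wider promoter window to 3.998 with the narrower one. Keeping the stronger 50% of sites left 605 by construction. The lists of replicates 2 and 1 alone gave 580 and 834 peaks (6 of the 834 mitochondrial), 1 and 3 chromosomes past the threshold (4 in the full set), and 7 and 9 gene lists (11 in the full set); fewer sites give these tests less power, and no further cause was tested. With GC-matched peaks below the threshold as background, an alternative chosen after seeing the data, 273 6-mers were more frequent in place of 574 and 358 less frequent in place of 494, so the balance turned; the cause was not tested. Leaving out sites with a signal under 25, also chosen afterwards, left 1165.

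Of 282 recomputed values for single classes, lists, chromosomes, 6-mers and motifs, and for the overlap of replicate 1's list with replicate 2's, 255 stayed the same, 26 lost their call and 1 moved. The signal at a named gene is the score of a single peak, so it shows only whether the peak was kept; among these genes, 3 (bli-6, ceh-43 and elt-2) had no site in the other series set, 6 had none among the stronger 50% of sites, and 10 had none in the narrower promoter window. The top 5 6-mers kept their call under all alternatives fixed beforehand. With unknown depth, the lower count in replicate 2 cannot be assigned to depth or to biology.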

Other observations

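The tests of gene arrangement and of weaker peaks were written before their results were seen; the values for groups other than tRNA genes were added afterwards. Signal at small RNA genes went on below the threshold. For small RNA genes, sites were counted here in or within 100 bp of the gene, not in the promoter window. By this count 481 tRNA genes had no called site. Of these, 60.3% held the summit of a weaker ranked peak there, against a mean of 9.53% and a highest value of 12.9% over 200 shifts. The shares were 27.6% for snoRNA genes (highest shift 16.2%) and 32.7% for snRNA genes (18.2%), while the 30% of spliced leader RNA genes was within the range of the shifts, which reached 35%. Of the 45 ribosomal protein genes with no called site, 80.0% held a weaker summit in the promoter window (highest shift 53.3%), and chemoreceptor genes, at 18.5%, lay below the lowest shift of 26.1%. Protein-coding genes as a whole were also above the shifts, though by less, at 35.7% against a highest shift of 32.45%. The threshold, rather than the absence of signal, may separate many tRNA and ribosomal protein genes with a site from those without. For tRNA genes this cannot be told apart from reads shared between copies, since 469 of 612 share their sequence and the 481 were not split by it. An untagged control would be needed to tell binding from general accessibility.

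A hypothesis that sites favour promoters between divergent genes was tested on 612 sites upstream of the nearest protein-coding 5′ end. A divergent 5′ end lay within 1000 bp upstream of that gene for 30.6% of sites and for 7.76% of 1224 positions at the same distances from genes with no site, an odds ratio of 5.22 (95% interval 3.96 to 6.93). This test was first run as a comparison of 596 genes nearest to these sites with 19090 genes with no site, which gave 30.9% against 16.4% and an odds ratio of 2.28 (95% interval 1.895 to 2.727), and then rerun against matched positions as its prediction had been written, so its final form was coded after a related result had been seen. The share at sites hardly differed between these forms, so the higher odds ratio came from the lower background share (7.76% against 16.4%). The size of the excess thus depends on how the background was drawn. A second hypothesis was that sites favour the first genes of closely spaced runs on a strand, an arrangement typical of worm operons. Of 596 genes nearest to these sites, 30.2% were followed by a gene on the same strand within 500 bp, against 17.4% of 19090 genes with no site, an odds ratio of 2.06 (95% interval 1.71 to 2.47). The test did not ask whether the gene was first in its run, and the genes with no site were not matched. It shows that genes nearest to a site are more often closely followed, and leaves the position in the run untested. That LIR-1 sites lie at compact, broadly used promoters is a possible reading of both results that was not tested. Expression was not measured here, so expression level and arrangement could not be separated.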
